A study of Homo sapiens and Mus musculus with 8 samples.

How the data were processed

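RNA-seq was done on 8 samples of 3 melanoma cell lines, 1 sample per group: untreated and UV-exposed WM983 and UACC257 (human), and untreated B16N (mouse), B16N after 2 and 5 weeks of UV and a B16N clone transfected with tagged Orai1, per the labels. The titles of the human UV samples hold the mark UV3 while their time label is week 2, and the time label was used. The growth protocol of the labels describes B16N for all samples, so the culture of the human lines is not known. Reads were aligned to GRCm38, per the submitters' processing notes, which name no other build, so the build behind the human tables is not known. The aligner, the counting and the test were not given in the sources used here.

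The authors deposited 5 tables of comparisons, 3 for B16N and 2 for the human lines. Each row holds a gene symbol, a log2 fold change, a test statistic used here as a score and a p-value, per the file headers. The deposited log2 fold changes of the mouse tables have the control in the numerator: 1357 genes had a row in a single mouse table, as a gene without reads in the other libraries would, and all 1357 had a negative deposited value and 0 a positive one. The sign was therefore turned, so that positive values mean higher in the treated sample. No such check was possible for the human tables, and their signs are given as deposited. The deposited p-value of each mouse row is the two-sided normal p of the deposited score (largest gap 5.0e-08 at 2 weeks), so the log2 fold change divided by the score gave the standard error (SE). The tables hold no counts or levels, so the depth per sample is unknown and no interval that needs it is given.

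The design drawn up before the data were examined assumed levels, with a 2-fold rule on values of at least 5. As the tables hold none, the level filter was replaced by a Benjamini-Hochberg adjusted p under 0.05, computed over all usable rows of each mouse table (14648, 14821 and 15041 rows) from the deposited p-values. A row without a symbol was left out of each mouse table, as were 3 rows without a p-value in that of the clone. The 2-fold minimum was kept, and counts without it are given beside it. A normal test of the difference of 2 changes, with both SE added in squares and Benjamini-Hochberg adjustment, compared treated samples with one another. This test counts the spread of the common control in both changes, and a control value common to both cancels in the difference.

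The 36 gene lists were fixed before the data were examined. The median log2 change of a list was placed among 10000 random lists of the same size whose members were drawn from the 200 rows nearest in SE, for lists of at least 5 members, in place of the planned match on mean expression. Members that shared their values with another symbol were left out. Named genes followed a rule: measured members of the store-operated Ca2+ entry list, the 10 largest rises and 10 largest falls per comparison, and up to 4 members per list with the largest passing differences. Some genes under this rule were not analysed here. The largest rises among genes with a row in all 3 mouse tables were added after the values were seen, and other genes named from the lists in a comparison passed in another one. Further members of the immediate early, pigment cell, inflammatory and NRF2 lists are named to show both directions, also after the values were seen.

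Agreement between comparisons was measured across genes by overlap, Pearson and Spearman correlation and covariance for genes of SE at most 0.5, against independent lists and against 100 simulations of unchanged samples with one control. The simulations assumed that control and treated sample share the smaller squared SE equally, which could not be checked without depth. They hold noise alone, while true changes found in a single comparison lower the observed correlation. Human and mouse genes were matched by symbol regardless of letter case.

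The procedure was tested on simulated data with 200 changed genes per comparison, all placed in rows of SE at most 0.5. Recovery among rows of larger SE is therefore not known. A call there was an adjusted p under 0.05 with no fold minimum, so the 2-fold rule was not tested. Noise followed the deposited SEs, so the false calls do not show whether those SEs are right. For UV at 2 weeks (14648 genes) it recovered 80% of 2-fold and 96% of 4-fold changes with 5 false calls. For UV at 5 weeks (14821 genes) it recovered 70% and 98% with 5 false calls, and for the clone (15041 genes) 81% and 100% with 5 false calls. No call had the wrong sign, and 7, 5 and 7 of 100 unchanged lists lay outside the central 95% of random lists, with noise drawn independently for each gene.

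Alternatives were fold minimums of 1.5 and 4, no filter, an adjusted p under 0.01, an SE of at most 0.5 or 0.3, symbols with shared values in or out, and setting the median of genes of SE at most 0.3 to 0. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.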

Results

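RNA-seq comparisons were available for 8 samples of 3 melanoma cell lines, with 1 sample per condition in the labels. B16N is a mouse melanoma line, and WM983 and UACC257 are human melanoma lines. Each line was profiled without treatment and after UV exposure, for 2 weeks in the 3 lines and also for 5 weeks in B16N. A further B16N sample was a clone grown after transfection with fluorescently tagged Orai1, the pore subunit of the store-operated Ca2+ channel. The comparisons address how UV exposure, and the overexpression of a Ca2+ entry channel, change the transcriptome of melanoma cells. The values were the authors' own comparisons of each treated sample with its untreated line, so levels and depth were unknown and no difference had a replicate check here. Controls and the clone were labelled day 0 and UV samples week 2 or 5, so weeks in culture cannot be told apart from UV. The number of libraries behind each p-value was not given, and a test on 1 library per group compares those libraries and not the conditions. The 3 mouse tables held 14648, 14821 and 15041 usable genes for UV at 2 weeks, UV at 5 weeks and the Orai1 clone. Mouse changes are given as treated against control on the log2 scale, with the standard error (SE) that the deposited test statistic implies and a Benjamini-Hochberg adjusted p computed over the table from the deposited p-values. Where the SE was above 1, the direction is given with its adjusted p but no fold. Symbols that shared their exact values with another symbol were counted among all genes and left out of the gene lists. Of genes passing with no fold minimum, these were 188 of 1124 at 2 weeks, 130 of 708 at 5 weeks and 548 of 3305 in the clone. The counts of changed genes therefore hold some values more than once.

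After 2 weeks of UV, B16N cells had higher levels of pigment cell genes, of glycolytic and hypoxia-responsive genes and of several immediate early genes. Some members of the inflammatory cytokine list were lower. Tyr, which encodes the rate-limiting enzyme of melanin synthesis, rose by a log2 fold change of 0.95 in the authors' deposited table (SE 0.10, adjusted p = 1.83e-18). The galectin gene Lgals3 rose (2.29, SE 0.28) and the chemokine gene Cxcl10 fell (-1.87, SE 0.12, adjusted p = 6.17e-55) in the authors' deposited table. In total, 51 genes passed an adjusted p of 0.05 with a change of at least 2-fold, 33 higher and 18 lower. With no fold minimum 1124 genes passed, 458 higher (40.7%) and 666 lower, and with the median change of genes of low SE set to 0 the share higher was 48.1% of 1079. Of 33 gene lists, 6 had medians above and 4 below the central 95% of random lists, where independent genes and lists would give 1.65 outside. Some lists share members, such as Slc2a1 and Pdk1 in the glycolysis and hypoxia lists, so chance can put more lists outside than this. Of the 4 below, the Wnt and the MAPK and PI3K medians went from -0.36 to -0.014 and from -0.23 to -0.15 with symbols of shared values included, and the interferon median from -0.21 to -0.096 with an SE of at most 0.5.

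The pigment cell list had 8 of 16 measured members higher and none lower, and 9 higher when adjusted over the list alone. Its median log2 change of 0.48 lay above all 10000 random lists matched on SE. Besides Tyr, the largest rises in the authors' deposited table were those of Gpnmb (0.86, SE 0.065), the transporter gene Slc45a2 (0.84, SE 0.11) and Dct (0.72, SE 0.081), an enzyme of the eumelanin pathway. The glycolysis list had 5 of 17 members higher and none lower, with 8 higher when adjusted over the list alone and a median of 0.40, above all random lists, which was 0.30 with symbols of shared values included. Pdk1, whose kinase holds back pyruvate dehydrogenase, rose by 1.28, the pyruvate kinase gene Pkm by 0.61, the glucose transporter gene Slc2a1 by 0.50 and the aldolase gene Aldoa by 0.35 in the authors' deposited table. In the hypoxia list 4 of 12 members were higher and 5 when adjusted over the list alone, among them Bnip3 (0.91, SE 0.23) and Ddit4 (0.47, SE 0.13) beside Pdk1 and Slc2a1 in the authors' deposited table. Car9, a carbonic anhydrase gene induced by low oxygen, had the largest rise by fitted value in the authors' deposited table (adjusted p = 6.25e-04). H2-DMb1, of the antigen presentation machinery, rose as well in the authors' deposited table (adjusted p = 0.0359), and both had an SE above 1.

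Immediate early genes had 4 of 16 members higher and none lower, also when adjusted over the list alone, with Fos at 1.46, SE 0.36, Dusp4 at 0.60, SE 0.13, Junb at 0.50, SE 0.14 and Ier2 at 0.45, SE 0.11 in the authors' deposited table. The lysosome list had 3 of 16 higher, led by the cathepsin genes Ctsb (0.88, SE 0.11) and Ctsd (0.52, SE 0.073) beside Bnip3 in the authors' deposited table. Nuclear-encoded respiratory chain genes had 4 of 27 members higher and 1 lower, and 7 and 1 when adjusted over the list alone, including Ndufb8 (0.84, SE 0.21) and Ndufa2 (0.76, SE 0.16) in the authors' deposited table. Among cholesterol biosynthesis genes 2 of 21 were higher, Insig1 (0.68, SE 0.14) and Sc5d (0.43, SE 0.11) in the authors' deposited table. Abca1, which exports cholesterol from the cell, fell by 0.95 on the log2 scale in the authors' deposited table (adjusted p = 0.00153).

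Other large rises in the authors' deposited table were those of the copper transporter gene Atp7a (3.13, SE 0.97), the glutathione transferase gene Gsta2 (2.12, SE 0.44), Pla2g2e (1.91, SE 0.61), the perlecan gene Hspg2 (1.60, SE 0.52), C2 (1.49, SE 0.50) and Nr4a3 (1.38, SE 0.42). The largest falls in the authors' deposited table, after Hapln1 (-3.29, SE 0.93) and the lipase gene Lipg (-2.94, SE 0.86), were those of Cxcl10, Hdac9 (-1.83, SE 0.62), Stum (-1.61, SE 0.27), the aggrecanase gene Adamts5 (-1.39, SE 0.30), Cyp26b1 (-1.34, SE 0.11), Neurl3 (-1.26, SE 0.31), Pknox2 (-1.14, SE 0.13) and Sox4 (-1.12, SE 0.094). Of the inflammatory list, 3 of 9 members fell and none rose, namely Tgfb2 (-0.92, SE 0.22), Csf1 (-0.82, SE 0.17) and Relb (-0.75, SE 0.23) in the authors' deposited table. When adjusted over the list alone, 5 were lower and 1 was higher, the chemokine gene Ccl2. Its SE was above 1 and its adjusted p over the whole table was 0.136. MAPK and PI3K pathway genes had 7 of 22 members lower, among them Pik3cb, which no longer passed with the median change set to 0, and none higher, and 8 lower with 1 higher when adjusted over the list alone, including the receptor gene Erbb3 (-0.69, SE 0.16) and Pik3r1 (-0.56, SE 0.14) in the authors' deposited table. In the pentose phosphate and hexosamine list, which also holds serine and one-carbon enzymes, Mthfd2 (-0.61, SE 0.081) and Psat1 (-0.42, SE 0.071) fell and no other of the 12 members passed in the authors' deposited table. None of the 6 measured store-operated Ca2+ entry genes passed, with Orai2 at -0.044, SE 0.13, Stim2 at -0.22, SE 0.37 and Saraf at 0.24, SE 0.14 in the authors' deposited table. Of 15 p53 targets and 16 nucleotide excision repair genes with values of their own, none passed either.

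**Figure D1:**
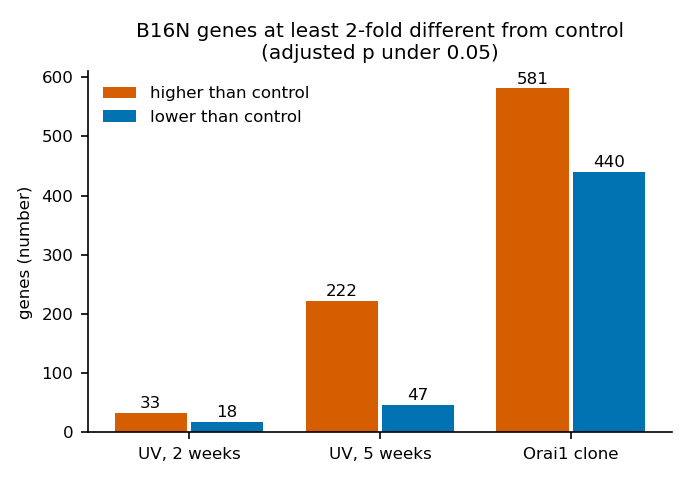
Bars give the number of B16N genes (y axis, count) at least 2-fold higher or lower than control with an adjusted p under 0.05, for UV at 2 weeks, UV at 5 weeks and the Orai1 clone (x axis). The counts were 33 and 18, 222 and 47, and 581 and 440.

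After 5 weeks of UV, most members of the oxidative stress (NRF2) list were higher in B16N. Integrated stress response genes, cholesterol biosynthesis genes, lysosomal genes and pigment cell genes were higher as well. Slc7a11, the cystine transporter gene, rose by a log2 fold change of 2.82 in the authors' deposited table (SE 0.18, adjusted p = 1.84e-50), and the growth regulator Myc fell by 1.34 on the log2 scale (adjusted p = 4.10e-09). Itpr2, an inositol trisphosphate receptor gene that releases Ca2+ from the endoplasmic reticulum, rose by 1.80 in the authors' deposited table (SE 0.20, adjusted p = 1.48e-15). In total 269 genes changed at least 2-fold, 222 higher and 47 lower, and 708 passed with no fold minimum, 455 higher and 253 lower. With genes of SE at most 0.5 alone, the 2-fold count was 172.

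The NRF2 list had 11 of 17 members higher and 1 lower, and 13 and 1 when adjusted over the list alone. After Nqo1 (adjusted p = 4.29e-04), a quinone reductase gene with an SE above 1, and Slc7a11, the largest in the authors' deposited table were the haem oxygenase gene Hmox1 (2.56, SE 0.49) and the metallothionein gene Mt2 (2.40, SE 0.18). The unfolded protein and integrated stress response list had 7 of 16 members higher and none lower, and 9 when adjusted over the list alone, led in the authors' deposited table by Trib3 (2.41, SE 0.49), Ppp1r15a (1.51, SE 0.33), Herpud1 (1.19, SE 0.21) and Cebpb (0.98, SE 0.22). Cholesterol biosynthesis had 8 of 21 members higher and none lower, and 9 when adjusted over the list alone, with Fdps (1.29, SE 0.19), Insig1 (0.92, SE 0.18), Cyp51 (0.87, SE 0.12) and Sc5d (0.82, SE 0.14) the largest in the authors' deposited table. Scd1, which makes monounsaturated fatty acids, rose by 1.06 in the authors' deposited table (adjusted p = 2.68e-11). The medians of these 3 lists were 0.75, 0.47 and 0.40, each above all 10000 random lists. With symbols of shared values included, the stress response median was 0.76. Of 33 lists, 12 lay above and 1 below the central 95% of random lists, where independent genes and lists would give 1.65. The commonly stable genes were among those above (median 0.22, percentile 99.1), with none of 14 passing. The glycolysis (0.21) and nuclear-encoded respiratory chain (0.15) medians, above the random lists too, did not exceed that of the stable genes. The antigen presentation list, also above, went from a median of 0.74 to 0.074 with an SE of at most 0.5, and none of its 9 members passed.

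Pigment cell genes had 8 of 16 members higher and 1 lower, also when adjusted over the list alone, with Tyr at 1.32, SE 0.15, Slc24a5 at 0.86, SE 0.16, Dct at 0.85, SE 0.15 and Pmel at 0.75, SE 0.15 in the authors' deposited table. The lower member was Mc1r (-0.65, SE 0.14), which was among the higher members at 2 weeks (0.41, SE 0.079) in the authors' deposited tables. Lysosomal genes had 4 of 16 higher and 5 when adjusted over the list alone, namely the autophagy receptor gene Sqstm1 (1.71, SE 0.17), Lamp2 (1.10, SE 0.19), Ctsb (1.09, SE 0.14) and Ctsd (0.95, SE 0.13) in the authors' deposited table by the table-wide adjustment. Of the pentose phosphate and hexosamine list, 5 of 12 members rose and 6 when adjusted over the list alone, including Shmt2 (0.92, SE 0.16), Taldo1 (0.76, SE 0.16), Mthfd2 (0.55, SE 0.13) and Psat1 (0.53, SE 0.11) in the authors' deposited table. Mitochondrially encoded genes had 5 of 13 higher and 8 when adjusted over the list alone, with mt-Co1 at 0.92, SE 0.14 and mt-Nd4 at 0.68, SE 0.16 in the authors' deposited table. In the glycolysis list only Aldoa passed over the whole table (0.44, SE 0.11 in the authors' deposited table), and 3 of 16 members were higher when adjusted over the list alone. Among p53 targets Plk2 (1.33, SE 0.39) and Mdm2 (0.56, SE 0.12), a gene that p53 induces and that limits p53, rose in the authors' deposited table, and 3 of 15 were higher when adjusted over the list alone.

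Among store-operated Ca2+ entry genes, Orai2 rose (0.49, SE 0.15, adjusted p = 0.033), while Stim2 stood at -0.05, SE 0.41 and Saraf at 0.33, SE 0.18 in the authors' deposited table. The 10 largest rises by fitted value were those of Ptprd, Tuba4a, Ccdc149, Fkbp11, Afap1l1, Pla2g4a, Nqo1, Nexn, Zfp991 and Eya1, each with an SE above 1 and with adjusted p-values from 2.91e-08 for Tuba4a to 0.0347 for Pla2g4a. With an SE under 1, Dkk3 (5.26, SE 0.85), the interferon-induced sensor gene Ifih1 (3.70, SE 0.97), S100a4 (2.50, SE 0.43), Hspb8 (1.83, SE 0.53), Timp3 (1.34, SE 0.40) and the elastic fibre gene Fbln5 (1.20, SE 0.22) rose in the authors' deposited table. Lyz2, a myeloid cell marker and the single immune marker of this kind with a value of its own, rose by 3.47 in the authors' deposited table (SE 0.70, adjusted p = 6.84e-05). The largest falls in the authors' deposited table were those of Hapln1 (-3.16, SE 0.98), the neurotrophic factor gene Nrtn (-2.99, SE 0.78), Klhdc7a (-2.12, SE 0.47), the protease gene Prss23 (-1.95, SE 0.17), Pcdhb19 (-1.92, SE 0.57), Megf10 (-1.88, SE 0.59), Adamts5 (-1.85, SE 0.38), Cd248 (-1.77, SE 0.53), Neurl3 (-1.75, SE 0.46) and Pknox2 (-1.61, SE 0.20). The receptor tyrosine kinase gene Axl (-1.48, SE 0.19), Erbb3 (-1.02, SE 0.24) and the MAPK feedback gene Dusp6 (-0.85, SE 0.15) also fell in the authors' deposited table.

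Both UV times were set against each other gene by gene. Of 10166 genes with values of their own in both tables, 381 had changes that differed between 5 and 2 weeks by a normal test of the difference (adjusted p under 0.05), 235 higher and 146 lower at 5 weeks. In the NRF2 list 10 of 17 members were higher at 5 weeks than at 2 weeks and 1 was lower, and in the stress response list 5 of 16 were higher. Immediate early genes had 4 of 16 members lower at 5 weeks than at 2 weeks. Slc7a11, Trib3, Scd1, Mthfd2 and Psat1 fell at 2 weeks and rose at 5 weeks, and their changes differed by 3.52, 3.07, 1.39, 1.16 and 0.96 on the log2 scale in the authors' deposited tables. Slc2a1 was lower at 5 than at 2 weeks (difference -0.93, adjusted p = 0.0202) in the authors' deposited tables. Tyr, Dct, Ctsb, Hapln1, Adamts5, Neurl3, Pknox2 and Erbb3 passed at both times in one direction.

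Of 147 genes that passed at both UV times, 117 (79.6%) changed in one direction, 59 higher and 58 lower. Independent lists of these sizes would share 13.0 higher and 11.3 lower genes. Across 7208 genes of SE at most 0.5 in both tables the correlation of the changes was r = 0.269, with a Spearman coefficient of 0.253, against 0.412 simulated for unchanged samples with one control. The covariance was 0.0312, against 0.0237 simulated, and genes are not independent replicates. The simulated values depend on the assumed share of the control and hold noise alone. An observed r below the simulated one therefore does not mean agreement below chance. In opposite directions, 24 genes were higher at 5 and lower at 2 weeks and 6 the reverse, where independent lists would share 18.5 and 7.88. The independent values take no account of SE, and genes of low SE pass more readily in both tables. Both comparisons used one control, which could not be divided, so its share in the excess over independent lists is not known. The comparisons of UV times and clone were 3 such relations in all.

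**Figure D2:**
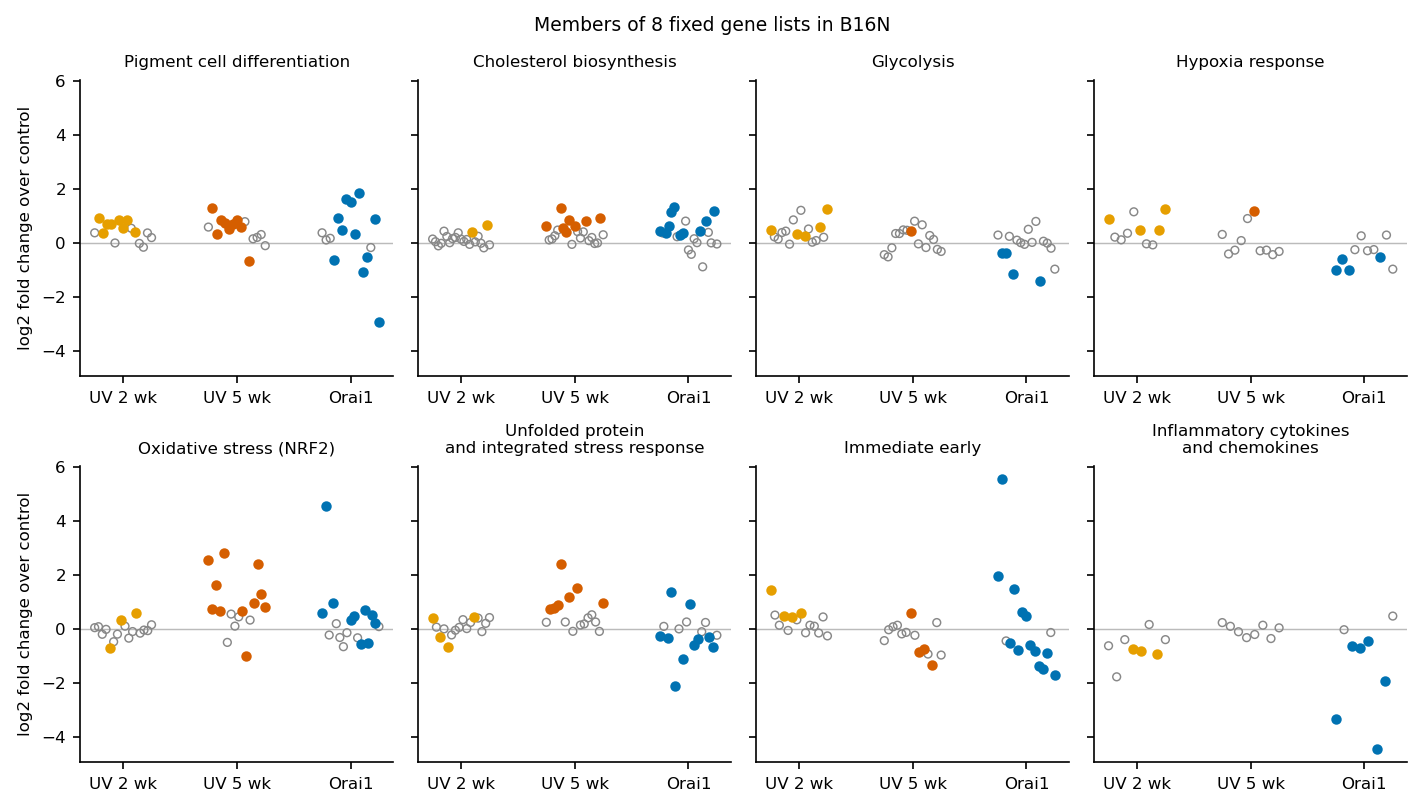
Each point is a member of a gene list fixed in advance, with its log2 fold change over control (y axis) after UV for 2 or 5 weeks and in the Orai1 clone (x axis), for members with SE at most 1 and values of their own. Filled points passed an adjusted p of 0.05 and open points did not. Of the 17 NRF2 members 11 were higher at 5 weeks, including Nqo1, which is not drawn.

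In the Orai1 clone, the Ca2+ store release gene Itpr2 and the Ca2+-regulated transcription factor gene Nfatc2 were lower than in control B16N, cholesterol biosynthesis genes were higher, and hypoxia and inflammatory genes were lower. Immediate early genes went both ways, with Fos, Fosb and Junb higher and a larger number lower. Nfatc2 fell by 6.66 on the log2 scale in the authors' deposited table (SE 0.33, adjusted p = 7.20e-89) and Itpr2 by 3.08 (SE 0.23, adjusted p = 1.43e-39). Orai1 itself was not analysed here, so the overexpression could not be checked on the transcript. In total 1021 genes changed at least 2-fold, 581 higher and 440 lower, and 3305 passed with no fold minimum, 1553 higher (47.0%) and 1752 lower. With the median change of genes of low SE set to 0, the share higher was 52.0% of 3325, so the larger direction turned. Of 33 gene lists, 2 lay above the central 95% of random lists (cholesterol biosynthesis and pigment cell). Another 5 lay below it (hypoxia, invasion, inflammatory, immediate early, and senescence and apoptosis). The medians of the other lists lay inside it, so their counts of passing members are not read as a shift of the list. The NRF2 (percentile 97.25), p53 target (97.03) and interferon (96.89) lists lay just inside the upper limit of 97.5, so a shift of these stays open. Of all genes with SE at most 0.5, 3270 of 9116 passed when adjusted among themselves. As a single clone was compared with its parental line, differences between clones are part of these counts.

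Of the store-operated Ca2+ entry genes, Orai2 rose (0.56, SE 0.13, adjusted p = 1.39e-04), and Stim2 (0.29, SE 0.33) and Saraf (-0.24, SE 0.15) did not pass in the authors' deposited table. The calcineurin and NFAT list had 1 of 12 members higher and 3 lower, and 5 and 4 when adjusted over the list alone, with its median at percentile 82.27 of the random lists. Nfatc1 stood at -1.36, SE 0.42, the calcineurin regulator gene Rcan1 at -0.38, SE 0.11 and the kinase gene Camk2d at 0.65, SE 0.19 in the authors' deposited table. Of the Ca2+ entry channel list, 1 of 10 members rose and 1 fell, also when adjusted over the list alone, P2rx5 with an SE above 1 (adjusted p = 0.0116) and Trpm7 (-0.43, SE 0.12) in the authors' deposited table. Of 11 genes of Ca2+ stores and export, the Golgi pump gene Atp2c1 (-0.63, SE 0.16) and Itpr2 fell and none rose in the authors' deposited table. Cholesterol biosynthesis had 10 of 22 members higher and none lower, and 11 when adjusted over the list alone, led in the authors' deposited table by Fdps (1.35, SE 0.15), Insig1 (1.18, SE 0.14) and Idi1 (1.17, SE 0.28). Its median was 0.38, at percentile 99.98 of the random lists. Mylip, which encodes a ubiquitin ligase, rose by 1.22 in the authors' deposited table (adjusted p = 3.17e-06).

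Pigment cell genes moved both ways, with 8 of 17 members higher and 4 lower, also when adjusted over the list alone, and a median of 0.39 at percentile 99.9. Rab27a (1.88, SE 0.51) and Slc45a2 (1.64, SE 0.11) rose and Ppargc1a (-2.93, SE 0.28) fell in the authors' deposited table, and Oca2 rose with an SE above 1 (adjusted p = 6.75e-04). Glycolysis genes had 4 of 17 members lower and none higher, also when adjusted over the list alone. The list as a whole was not shifted, with a median of 0.001 at percentile 55.6. Of the 4, Hk1 and Hk2 no longer passed with the median change set to 0, and Pgk1 stood at -1.42, SE 0.16 and Pfkp at -1.14, SE 0.18 in the authors' deposited table. Hypoxia genes had 4 of 14 lower and none higher, also when adjusted over the list alone, namely the oxygen sensor gene Egln1, Bnip3, Ndrg1 (-0.59, SE 0.10) and Kdm3a (-0.52, SE 0.13) in the authors' deposited table. The stress response list had 2 of 16 members higher and 8 lower, also when adjusted over the list alone, with Xbp1 at 1.39, SE 0.15, Trib3 at -2.11, SE 0.17 and Herpud1 at -1.13, SE 0.18 in the authors' deposited table. NRF2 genes had 8 of 17 higher and 2 lower, and 8 and 3 when adjusted over the list alone, with Nqo1 (4.57, SE 0.66) and Gclm (0.96, SE 0.18) the largest rises in the authors' deposited table.

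Immediate early genes had 5 of 16 members higher and 8 lower, also when adjusted over the list alone. The AP-1 genes Fosb (5.55, SE 0.67), Fos (1.96, SE 0.30) and Junb (1.48, SE 0.14) rose while Etv5 fell (-1.70, SE 0.26) in the authors' deposited table. Ier2 and Ier3 rose as well, and Jun, Jund, Dusp4, Dusp6, Spry2, Spry4 and Myc were the other members that fell. Of the inflammatory list, 6 of 9 members fell and none rose, also when adjusted over the list alone, with Tgfb1 at -4.44, SE 0.88, Ccl5 at -3.32, SE 0.43 and Tgfb2 at -1.92, SE 0.25 in the authors' deposited table. Interferon response genes had 7 of 21 higher and 1 lower, and 8 and 1 when adjusted over the list alone, where Cxcl10 fell (-4.89, SE 0.15) and Ifih1 (2.94, SE 0.93), Gbp2 (1.88, SE 0.54) and Ifi27 (1.43, SE 0.22) rose in the authors' deposited table. The invasion list had 5 of 14 members lower and 1 higher, and 6 and 1 when adjusted over the list alone, with Timp2 (-0.97, SE 0.088), Zeb2 (-0.60, SE 0.12) and Cd44 (-0.57, SE 0.096) lower and the urokinase receptor gene Plaur (0.68, SE 0.23) higher in the authors' deposited table. In the dedifferentiated state list, 2 of 11 members rose and 4 fell, also when adjusted over the list alone, where Pou3f2 (-2.89, SE 0.54) and Axl (-2.75, SE 0.15) fell and Ccn1 (2.22, SE 0.10) rose in the authors' deposited table. The cell cycle list had 5 of 22 members higher and 3 lower, also when adjusted over the list alone, with its median at percentile 67.15 of the random lists. Cdc20 (0.62, SE 0.20) and Mcm2 (0.48, SE 0.14) were higher and the cyclin gene Ccnd1 (-1.83, SE 0.12) and Mcm4 (-0.59, SE 0.12) lower in the authors' deposited table. Senescence and apoptosis genes had 2 of 11 higher and 4 lower, and 2 and 5 when adjusted over the list alone, with Mcl1 (0.60, SE 0.11) higher and Bcl2l1 (-0.82, SE 0.10), both survival genes, lower in the authors' deposited table. Lyz2 rose here too (2.78, SE 0.64) in the authors' deposited table.

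The largest falls by fitted value in the clone were those of Xlr3c, Pcdh1, Zdhhc15, Adssl1, Cyba, Xlr3a, Adam12, Xlr3b, Nfatc2 and Birc3. Of these, Xlr3a (-8.05, SE 0.74) had an SE under 1 in the authors' deposited table beside Nfatc2, and Xlr3a, Xlr3b and Xlr3c are near-identical neighbours whose reads may not be separable. The largest rises by fitted value were those of B4galnt2 (9.86, SE 0.84), Arhgef15 (8.52, SE 0.73) and the basement membrane collagen gene Col4a1 (7.47, SE 0.61) in the authors' deposited table, with Tram1l1, Sult5a1, Krt78, Ptprd, Fkbp11, H2-DMb1 and Afap1l1 at an SE above 1.

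UV exposure and the Orai1 clone were then compared. Of 392 genes that passed both at 5 weeks of UV and in the clone, 358 (91.3%) changed in one direction, 204 higher and 154 lower. Independent lists would share 43.8 higher and 30.0 lower genes. The correlation across 7172 genes was r = 0.489 (Spearman 0.506), against 0.407 simulated, and the covariance was 0.106 against 0.0236 simulated. For 2 weeks of UV and the clone, 408 of 505 shared calls (80.8%) had one direction, 110 higher and 298 lower, where independent lists would share 45.3 and 79.7. The correlation was r = 0.305 (Spearman 0.331) against 0.457 simulated, and the covariance was 0.0552 against 0.0248 simulated. The simulated values carry the same assumption on the control, and r below the simulated one does not mean agreement below chance. In opposite directions, 33 genes were higher at 5 weeks and lower in the clone and 1 the reverse, against 52.3 and 25.1 for independent lists. For 2 weeks and the clone these were 69 and 28, against 55.9 and 64.6. The independent values take no account of SE here either. The control was common to these comparisons and could not be divided, so its share in the excess over independent lists is not known.

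Insig1, Fdps and Ctsb passed in one direction after 5 weeks of UV and in the clone, as did Axl and Erbb3, which were lower. Itpr2 went opposite ways, and its UV change at 5 weeks exceeded that of the clone by 4.88 on the log2 scale in the authors' deposited tables (adjusted p = 6.44e-54). Trib3, Herpud1, Dct and Lamp2 were also higher at 5 weeks and lower in the clone, with differences of 4.52, 2.31, 1.46 and 1.70 in the authors' deposited tables. Against 2 weeks of UV, 8 of 17 glycolysis genes and 5 of 12 hypoxia genes were lower in the clone and none higher by the test of the difference. Bnip3 differed by 1.91 and Pfkp by 1.59 between 2 weeks of UV and the clone in the authors' deposited tables. In all, 635 of 10278 genes differed between 5 weeks of UV and the clone, and 1351 of 10218 between 2 weeks of UV and the clone.

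**Figure D3:**
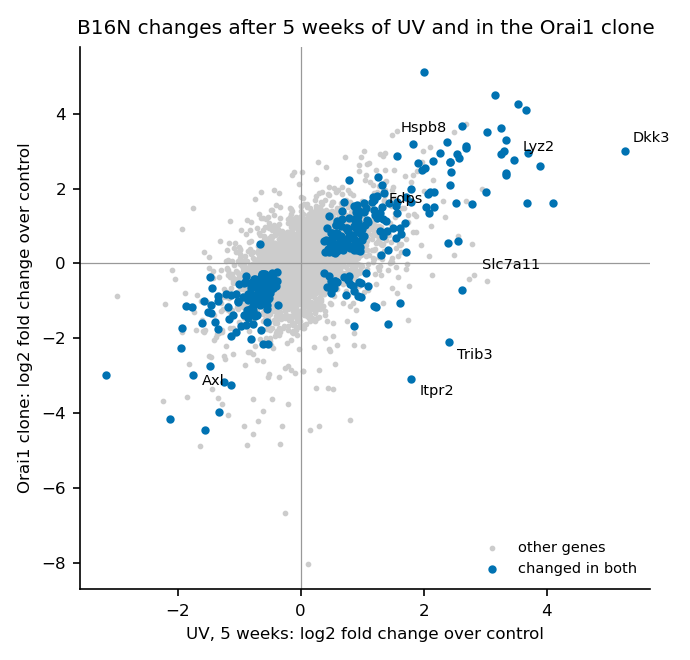
Each point is 1 of 8927 genes with SE at most 1 in both comparisons, with its log2 fold change over control after 5 weeks of UV (x axis) and in the Orai1 clone (y axis). Blue points passed an adjusted p of 0.05 in both comparisons, 333 of 366 of them in one direction.

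In WM983, cholesterol and fatty acid synthesis genes and pigment cell genes had positive values, and cyclin genes had negative ones. The human tables do not say which sample is the numerator, so their signs are given as deposited and not as rises or falls. All 10 listed cholesterol biosynthesis genes were positive in the authors' deposited table for WM983, from 1.07 for LSS to 2.49 for INSIG1, with STARD4 at 2.16 and MSMO1 at 1.66. The fatty acid genes FADS2 (2.44), FADS1 (1.33) and ACSS2 (1.01) were positive too in the authors' deposited table. TYRP1 (3.73) and the melanocyte antigen gene MLANA (2.14) were the 2 listed pigment genes in the authors' deposited table.

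Both human tables listed the same 420 genes. In WM983, 419 of the 420 were at least 2-fold different, 218 genes were positive and 202 negative, and 418 had a deposited p under 0.05, with 351 at the smallest value of 5e-05. The table thus gives no share of changed genes. The other large positive values in the authors' deposited table were those of LBH (3.25), RFTN2 (2.74), ATP6V0A4 (2.72), FAM163A (2.61), MAMDC2 (2.58), ZNF280A (2.33) and the actin capping gene CAPG (2.19). Among the most negative in the authors' deposited table were the keratin gene KRT18 (-3.12), MYH14 (-2.95), HIST1H4F (-2.85), the immediate early gene EGR3 (-2.69), CHIC1 (-2.68), MYADM (-2.35), PLEKHA4 (-2.35), RAC2 (-2.32) and ZNF521 (-2.26). CCND1 (-1.79) and CCNE1 (-1.07) were the listed cell cycle genes in the authors' deposited table. Among Ca2+ entry channels TRPC1 was at 1.15, MCOLN3 at -1.03 and the mechanosensitive channel gene PIEZO2 at -2.06 in the authors' deposited table. Of antigen presentation genes, HLA-F (1.14) was positive and the peptide transporter gene TAP2 (-1.18) negative in the authors' deposited table. Of the invasion list, ITGAV (1.35), MMP15 (1.16) and SNAI2 (1.09) were positive and SNAI1 (-1.05) was negative in the authors' deposited table.

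In UACC257, these cholesterol and pigment genes stood near 0. As set out below, the 420 genes may have been chosen for a change in WM983 and none in UACC257, which would by itself give such values. Of the 10 cholesterol genes 3 were positive and 7 negative in the authors' deposited table, with INSIG1 at -0.31 and MVD at 0.22, and TYRP1 (-0.22) and MLANA (-0.25) were slightly negative. A single gene reached 2-fold by the unrounded values of the authors' deposited table, the small nucleolar RNA SNORA24 (-1.27, deposited p = 0.0336). The highest in the authors' deposited table were the coagulation inhibitor gene TFPI (0.72), RNASE4 (0.63) and FOXD1 (0.56), and SNORD104 (-0.70), POLR2I (-0.66) and AMN1 (-0.60) were among the lowest. CCNE1 was at 0.40, TRPC1 at -0.49 and PIEZO2 at -0.34, with deposited p-values of 0.0323, 0.0336 and 0.0347 in the authors' deposited table. In all, 42 of the 420 genes had a deposited p under 0.05, the smallest being 0.0256, and 175 were positive and 245 negative. WM983 and UACC257 had the same sign for 183 of the 420 genes (43.6%), 78 positive and 105 negative in both.

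**Figure D4:**
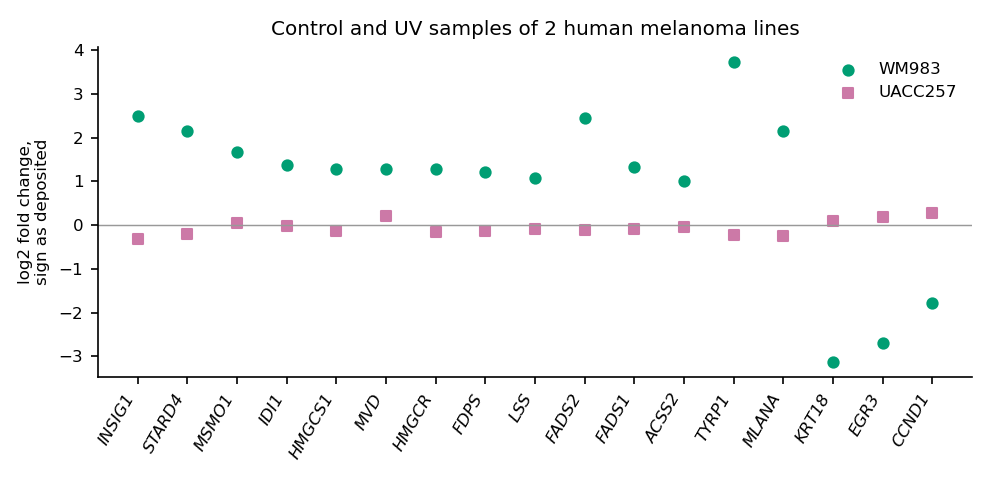
Points give the log2 fold change of the authors' deposited tables (y axis, sign as deposited) for 17 named genes (x axis) in WM983 (circles) and UACC257 (squares). The 9 cholesterol genes drawn lie from 1.07 to 2.49 in WM983 and from -0.31 to 0.22 in UACC257. The listed genes may have been chosen for a change in WM983 and none in UACC257.

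Genes listed for the human lines were matched by symbol to B16N. Of 220 matched genes with values of their own at 2 weeks of UV, 97 (44.1%) had in WM983 the sign of the B16N change, and 107 had it in UACC257. At 5 weeks these were 115 of 219 (52.5%) and 103. INSIG1 and FDPS, positive in WM983, were among the genes higher in B16N at 5 weeks. As the direction of the human tables is open, these shares describe signs only.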

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

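The tests of explanations in this part were all chosen after the results were seen, while the comparison of the UV times was planned.

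The difference between 5 and 2 weeks of UV in B16N passed for 381 of 10166 genes. Named genes whose UV change was higher at 5 weeks (difference on the log2 scale between the authors' deposited tables) included the stress response genes Slc7a11 (3.52), Trib3 (3.07), Hmox1 (2.50), Mt2 (2.44), Sqstm1 (1.79), Herpud1 (1.23) and Atf4 (1.06). Metabolic genes higher at 5 weeks in the authors' deposited tables included Scd1 (1.39), Abca1 (1.29), Mthfd2 (1.16), Shmt2 (1.06), Fdps (1.04), Psat1 (0.96), Idh1 (0.75), Mdh1 (0.74), Me1 (0.70), Cyp51 (0.66), mt-Co1 (1.02) and mt-Nd4 (0.85). Ca2+ release and uptake genes Itpr2 (1.85) and Mcu (0.96), the lysosomal gene Lamp2 (1.30), Mdm2 (0.71), Hsph1 (0.55), S100a4 (2.04) and Fbln5 (1.23) were also higher at 5 weeks in the authors' deposited tables. Tuba4a (8.08), Eya1 (7.23), Nqo1 (6.96) and Dkk3 (6.74) had an SE above 1 in at least 1 of the authors' deposited tables, so these fitted differences are no bound on a fold.

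Genes whose UV change was lower at 5 than at 2 weeks in the authors' deposited tables included Nrtn (-3.49), Prss23 (-1.41), Col5a1 (-1.40), Myc (-1.20), Axl (-1.10), Slc2a1 (-0.93), Spry2 (-0.90), Dusp4 (-0.83), Dusp6 (-0.71), Lmnb1 (-0.68), Tnfrsf12a (-0.57) and Pkm (-0.47). Time of exposure cannot be separated from other differences between the single samples. No biological explanation was tested for these genes.

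Genes gained at 5 weeks of UV were largely gained in the Orai1 clone as well. Over all genes, 1553 of 15041 were higher in the clone and 458 of 14648 at 2 weeks. Of 93 genes with values of their own that were at least 4-fold higher at 5 weeks, 66 (71.0%) were also higher in the clone and 5 (5.38%) at 2 weeks. Chance low values in the common control would raise these genes at 2 weeks too, but the median log2 change there of the 62 shared genes with a row was 0.159 (95% interval -0.30 to 0.45), against 3.34 at 5 weeks and 3.04 in the clone. Immune cells in the culture stay open, since 1 of 6 immune markers with a row at 5 weeks, Lyz2, was called and the others shared their values with another symbol. A library or culture batch common to the 5-week and clone samples could give the excess covariance of 0.0828 and cannot be told apart from UV and Orai1, as the labels name no batch.

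WM983 and UACC257 had opposite signs for 237 of the 420 listed genes, and these differences between the lines were not tested. The UACC257 table held no p-value below 0.0256, although uniform p-values would put 10.8 genes there, which argues against a table with no UV effect and no selection of genes (exact binomial p = 3.50e-05, with genes not independent). A count of 44 genes lay between the smallest p-value and its double. These values are consistent with genes chosen for a change in WM983 and none in UACC257, so the small UACC257 changes may reflect that choice. A weaker response of UACC257 to UV stays open and was not tested.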

How the results depend on the processing

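The settings with an adjusted p under 0.01, a limit on the SE and symbols with shared values in or out were chosen after seeing the data, and the others before.

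The counts depended on the thresholds, as each setting changes the rule itself. A 2-fold difference alone, with no filter, gave 1860 genes at 2 weeks, 2099 at 5 weeks and 3345 in the clone. A 1.5-fold minimum gave 269, 526 and 2049 genes, and a 4-fold minimum 7, 112 and 381. An adjusted p under 0.01 with no fold minimum gave 735 genes at 2 weeks and 430 at 5 weeks. With an SE of at most 0.5 the 2-fold count at 5 weeks was 172, since genes of larger SE were left out. In WM983 a 4-fold minimum left 42 genes, and in UACC257 12 genes passed 1.5-fold and 0 passed 4-fold. Of the 183 genes with one sign in both human lines, 1 was at least 2-fold different in both. With a 2-fold minimum in B16N at 2 weeks fewer genes entered, and 5 human and mouse genes shared a sign in place of 97. These counts are of sets of unlike size and do not compare the shares. Other settings left 50 values of counts and overlaps within 1.5 times the reported ones.

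Among list medians and single genes 391 values kept their direction and side of the threshold, 7 medians moved, 11 genes no longer passed and none reversed. With the median of genes of low SE set to 0, the genes that no longer passed were Atf4, Cd44, Hspa4, Mcu, Me1, Pik3cb and Timp2 at 2 weeks and Hk1, Hk2, Npc1 and Scd1 in the clone, because the shift of -0.024 at 2 weeks and -0.032 in the clone took small changes past the threshold. With symbols of shared values included, the medians of the glycolysis and MAPK and PI3K lists at 2 weeks went to 0.30 and -0.15, that of the Wnt list to -0.014, and those of the stress response and lysosome lists at 5 weeks to 0.76 and 0.24. With an SE of at most 0.5 the interferon median at 2 weeks was -0.096 and the antigen presentation median at 5 weeks 0.074. The cause was not tested.

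The correlation of 5 weeks and the clone was 0.487 with an SE of at most 0.3, that of both UV times 0.269, and that of 2 weeks and the clone 0.320. Other pseudocounts, filters on levels and rescaling of the human tables were not run, as the tables hold no levels, and the alternatives for Orai1 were not run, as Orai1 was not analysed here. No paired analysis was possible because each group has 1 sample and no replicate numbers link the groups. Depth is unknown, so whether an SE above 1 comes from few reads is not known, and no fold over control is given for such genes.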

Other observations

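The tests in this part were all chosen after the results were seen.

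Many unrelated symbols of the mouse tables shared identical values, with 4233 rows at 2 weeks, 4339 at 5 weeks and 4382 in the clone having a partner. Of pairs at 2 weeks with an SE of at most 0.3, 532 were listed in all 3 tables, and all 532 (100%) shared values in each, which equal low counts would not give. The check left out shared values of larger SE, so it does not speak to equal low counts there. For these 532 pairs a candidate explanation is that the values of one row were given to both symbols. A value under a symbol with a partner may therefore belong to that partner. Of 43 ribosomal protein rows at 2 weeks, 23.3% had an SE over 0.5, a smaller share than the 38.1% of all rows. Rows of minor transcripts under a gene's symbol, or reads lost to pseudogene copies, could both give such rows and cannot be told apart here.

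The sign of the WM983 table stays open. Of 21 listed genes that changed in B16N at 5 weeks, 13 (61.9%, Wilson interval 40.9 to 79.2) had the same sign in WM983, against 5 of 14 (35.7%, 16.3 to 61.2) at 2 weeks. Both intervals include 50%, so positive values may or may not mean higher after UV.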
